A study of Homo sapiens with 9 samples.

How the data were processed

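HEK293T cells were transfected with plasmids for TALE-VP64 activators against IL1RN, for TALE-VP64 activators against HBG1, or for GFP. Per the labels' protocols, plasmids were delivered by lipofection, total RNA was extracted on columns with DNase digestion, and mRNA was isolated on magnetic beads. Double-stranded cDNA was made with random hexamers, cut and tagged with Nextera transposase, and sequenced on an Illumina instrument. The labels state no strand-specific step, so reads of overlapping antisense genes cannot be told apart.

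The deposited values are whole-number read counts per RefSeq transcript, not normalized, in a single table of the whole series. Per the submitters' processing notes, the processing used CASAVA, Bowtie2, SAMtools, R 3.1.2, DESeq2 1.6.2, DESeq and the hg19 build; the notes give no roles or order. How a read that matches several transcripts or gene copies was counted is not given in the sources used here. Counts of near-identical genes such as HBG1 and HBG2 are therefore uncertain apart and were also added together. The division of IL1RN counts over its transcripts depends on the same unknown step.

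The labels name 9 samples, 3 per group, and the tests were planned for 9 libraries. The table used here holds 5 of them: 2 of IL1RN TALE, 1 of HBG1 TALE and 2 of GFP. The 4 other samples were not analysed here. Columns were matched to samples by name, and 0 columns belonged to other samples. Groups and replicate numbers come from the sample titles. With 5 libraries and 3 groups the fits have 2 residual degrees of freedom, and 1 group has no replicate.

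The table has 40709 transcript rows, and 1 further row without a transcript name, which held 0% of the counts, was left out. Gene symbols came from the RefSeq gene table for 39324 transcripts and from the GENCODE annotation for 516. The 869 others stayed under their own identifiers and held at most 1.22% of a library's counts. Transcripts of a gene were summed, which gave 24407 gene rows. This was decided after the table was seen, and a test of the transcript rows was added as an alternative. The annotation at hand is of a later build than hg19, so it was used for names, GC content and transcript length, and no coordinates are printed. Library totals ran from 9480984 to 19708455 counts.

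Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15). The 18413 genes kept were fitted in edgeR 4.0.16 with TMM factors of 1.00, 0.788, 1.18, 0.899 and 1.19 for IL1RN TALE 1 and 2, HBG1 TALE 1, and GFP 1 and 2. The main test was edgeR's robust quasi-likelihood F test on the counts with 1 coefficient per group, in 1 fit over all libraries so that the groups share an estimate of the spread. Contrasts gave IL1RN TALE against GFP, HBG1 TALE against GFP, and IL1RN TALE against HBG1 TALE. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 0.700 and the median prior degrees of freedom were 8.93. SEs were derived from the log2 fold change and its F statistic. R was version 4.3.3.

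Of 27 gene lists fixed from general knowledge before the data were examined, 25 had at least 5 measured members. The beta-globin cluster had 4 and the genes encoded in mitochondria had 0 in the table. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, 2-sided, and adjusted over the 25 lists in each comparison. Camera asks whether a list moves against the other genes. Alternatives were an estimated correlation and fry. Members were also tested one by one with the p adjusted over the list alone.

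The genes named in the text follow a rule also fixed before the data were examined. It takes IL1RN, HBG1 and HBG2, the members of the IL-1 family and beta-globin clusters that pass the filter (as counts, and by name at an adjusted p under 0.05), the 10 strongest called genes in each direction whose groups do not overlap, and for each called list the 3 measured members with the smallest p. A gene could be added to complete a count of 5 or fewer. A few genes that the rule takes are not reported here. HRC and C19orf84 were added that way. HBBP1, IL1A, CKAP2L and OR51B4, which pass the filter but were not called, and IL1B, HBB and HBE1, which do not pass it, were singled out after their values were seen.

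CPM of single genes use TMM-scaled totals and have exact Poisson 95% limits. Ratios of pooled counts have exact binomial limits. Shares have Clopper-Pearson limits. Where a group had 0 counts, 3 counts over the group were taken as the limit. CPM of olfactory receptors and other silent gene families, and ribosomal RNA shares, are on the raw totals. Reads carry no molecular identifiers, so limits cover counting error only. The GC and length trends used 14161 genes with more than 200 counts in total, of which 94.2% had a GC value. No transcript with more than 100 counts had identical counts in all libraries, and no pair of libraries agreed within sampling noise, so none was treated as a repeat of another.

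Alternatives fixed before the data were examined were library factors by the median of ratios (RLE), no filter beyond 1 count, a filter of at least 50 counts in 3 libraries, DESeq2 1.42.0, no robust estimation, only the libraries of the groups compared, the replicate number as a block, each library left out in turn, an adjusted p under 0.01 and a test against a fold change of 1.5. Added after the data were seen were per-library lowess offsets on GC content and length (span 0.4), these with the replicate block, a block with crossed GFP numbers, transcript rows, and fitted fold changes in the correlation of the TALE responses. The scale of that correlation, differences of group means of log2 CPM, was also settled after both values had been seen. RLE factors shifted the log2 fold changes by medians over all genes of −0.05, −0.03 and −0.03 in the 3 comparisons.

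The tests were tried on simulated counts with the real means and library sizes. In these, 200 genes with means above 1 CPM were changed by known folds. Each gene was drawn at the spread fitted as a trend on expression level, without further variation between genes. The shares found can therefore overstate what the tests find in the real libraries. Libraries were drawn independently, without the GC and olfactory receptor differences between the real ones. Over 18413 genes, edgeR made 0, 1 and 5 false calls in the 3 comparisons and DESeq2 made 48, 89 and 99. The chance correlation of responses that share controls came from 100 simulations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for counting, intervals and plots.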

Results

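RNA-seq libraries of HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, were compared after transfection with plasmids for 1 of 2 artificial transcriptional activators or for GFP. Each activator was a transcription activator-like effector (TALE), a protein whose repeats are engineered to bind a chosen DNA site, fused to the VP64 activation domain. One set targeted IL1RN, which encodes the secreted antagonist of the interleukin-1 receptor. The other targeted HBG1, which encodes a fetal gamma-globin of the beta-globin cluster. Cells that received GFP plasmids were the control, and the series asks what each activator does at its intended gene and at the other genes of the genome.

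The labels list 9 samples, 3 per group. Of these, 5 libraries were analysed here: IL1RN TALE replicates 1 and 2, HBG1 TALE replicate 1, and GFP replicates 1 and 2. The other 4 samples were not analysed here. The series' design describes triplicate transfections but names no days or batches, so p-values measure the spread between these libraries, part of which may be technical. The single HBG1 TALE library has no replicate, and the tests assume that it varies like the other groups. The libraries held 9480984, 16596194, 10178055, 19708455 and 18954835 read counts in that order, assigned by the authors to RefSeq transcripts. Transcript counts were summed to genes, and 18413 genes passed the filter on low counts. Counts-per-million (CPM) values are on TMM-scaled library sizes unless stated, and intervals are 95% exact Poisson or Clopper-Pearson limits that cover counting error only.

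The 5 libraries did not group by plasmid. Across the tested genes, the 2 IL1RN TALE libraries correlated at r = 0.907 and the 2 GFP libraries at r = 0.839 on log2 CPM, against a mean of 0.905 over the 8 pairs from different groups. Without TMM, with 0.5 added to CPM, over 14161 genes with more than 200 counts in total, the values were 0.819, 0.683 and a mean of 0.816. These correlations are across genes, which are not independent replicates. GC-rich genes were low in IL1RN TALE replicate 2 and GFP replicate 1 (Spearman's rho with GC content across genes −0.484 and −0.606) and high in IL1RN TALE replicate 1, the HBG1 TALE library and GFP replicate 2 (0.292, 0.484 and 0.531). Olfactory receptor genes, which are silent in most cells outside the nose, divided the libraries another way, by replicate number. Of 376 olfactory receptor transcripts, 59.8% (54.7–64.8) had at least 1 count in IL1RN TALE replicate 1, 77.1% (72.5–81.3) in the HBG1 TALE library and 73.9% (69.2–78.3) in GFP replicate 1. The share was 4.79% (2.86–7.46) in IL1RN TALE replicate 2 and 10.4% (7.48–13.9) in GFP replicate 2. Ribosomal RNA transcripts took 9.92%, 0.902%, 13.6%, 1.05% and 2.90% of the counts in the order of libraries given above. Both the GC difference and the olfactory receptor difference put 1 IL1RN TALE and 1 GFP library on each side, so values for single library pairs are given beside the pooled ones. The labels do not say whether a replicate number marks a shared preparation.

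**Figure D1:**
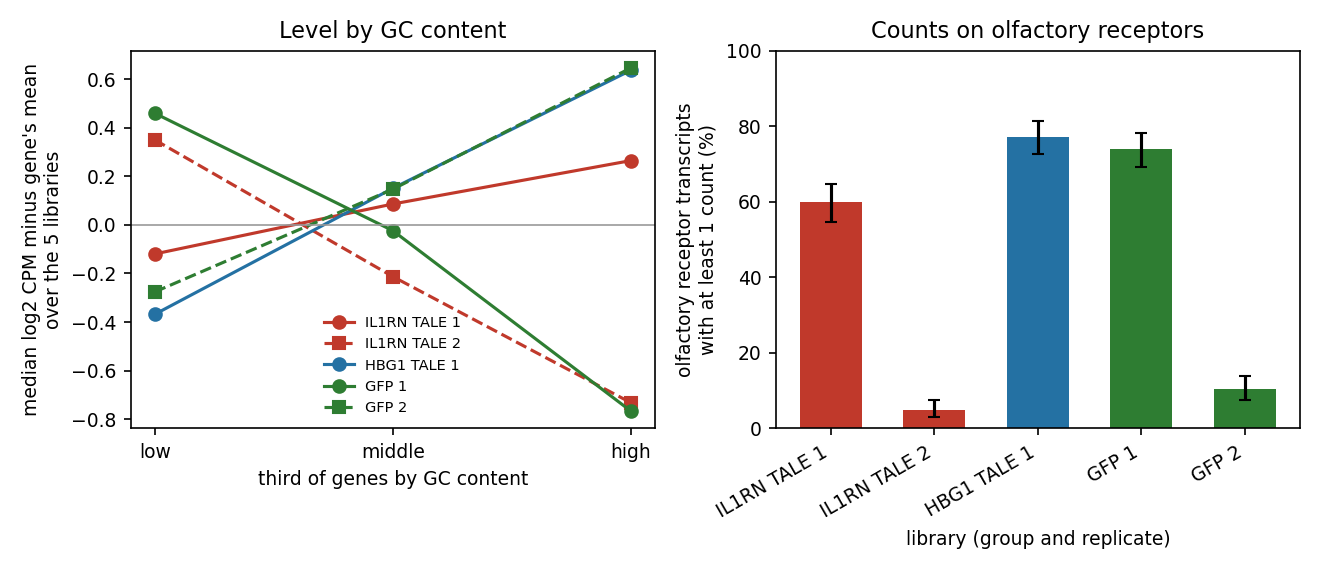
Left, the median over genes of log2 CPM minus the gene's mean over the 5 libraries, by tertile of genes on GC content, with 1 line per library; in the GC-rich tertile it is −0.73 in IL1RN TALE replicate 2 and −0.77 in GFP replicate 1, and 0.26 to 0.65 in the other libraries. Right, the percent of 376 olfactory receptor transcripts with at least 1 count per library (bars, with 95% Clopper-Pearson limits), which is 59.8 to 77.1 in 3 libraries and 4.79 and 10.4 in the others.

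IL1RN, the intended target of the first TALE set, was 51.7 ± 24.1 CPM (SD, n = 2) with the IL1RN TALEs and 1.94 ± 2.61 CPM (SD, n = 2) with GFP. Its counts were 328 and 898 in the IL1RN TALE libraries, 67 and 2 in the GFP libraries and 12 in the HBG1 TALE library, which are 34.6 (31.0–38.6), 68.7 (64.3–73.4), 3.78 (2.93–4.81), 0.0884 (0.0107–0.319) and 0.998 (0.516–1.74) CPM. Pooled over the libraries of each group, the ratio of IL1RN TALE to GFP was 31.8 (24.9–41.1). GFP replicate 1 set most of the control level. Against it the ratio was 9.14 (7.01–12.1) for IL1RN TALE replicate 1 and 18.2 (14.2–23.6) for replicate 2, and against GFP replicate 2 it was 391 (107–3245) and 777 (215–6428). Of these pairs, IL1RN TALE replicate 2 with GFP replicate 1 and IL1RN TALE replicate 1 with GFP replicate 2 lie on the same side of the GC difference, and the same-numbered pairs lie on the same side of the olfactory receptor difference. All 4 pairs were in the same direction. The fitted log2 fold change was 4.74 (SE 1.41), with an adjusted p of 0.99998 over the 18413 genes in edgeR's quasi-likelihood test, so IL1RN was not called. Adjusted over the list alone, IL1RN was 1 call among the 5 measured genes of the IL-1 family cluster (adjusted p = 0.0329). Without GFP replicate 1, IL1RN was called genome-wide, at a log2 fold change of 9.06 and an adjusted p of 0.0131, where the adjusted p ranged from 0.0131 to 1 over its alternatives. The 4 annotated IL1RN transcripts, NM_173841, NM_173842, NM_000577 and NM_173843, took similar parts of the counts in IL1RN TALE replicate 2, with 219, 216, 238 and 225.

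The neighbours of IL1RN in the IL-1 family gene cluster stayed near the limit of detection or did not pass the genome-wide test, which IL1RN itself did not pass either. Of the 13 cluster genes in the list, 12 were in the table and 5 passed the filter, while the 7 others held 36 counts in all 5 libraries together. IL1B, which encodes interleukin-1 beta, had 3, 0, 6, 9 and 1 counts in the order IL1RN TALE 1 and 2, HBG1 TALE, GFP 1 and 2. IL1A had 11, 2, 13, 14 and 3. The cluster was called higher by limma's camera test (adjusted p = 0.00209, median log2 fold change 1.11, 4 of 5 members positive). It was led by IL1RN itself, by PSD4, an exchange factor for ARF GTPases (log2 fold change 1.27, SE 1.22), and by IL36B (1.11, SE 2.37). PSD4 had 105, 27, 67, 13 and 106 counts and IL36B 6, 0, 6, 5 and 0. CKAP2L, which also passed the filter, had 207, 834, 251, 1041 and 802 (−0.14, SE 0.83). The target is itself a member, and IL36B, whose value is the median, reached the filter's cutoff in IL1RN TALE replicate 1 alone. The call is therefore no independent evidence on the neighbours. The call was lost with an adjusted p of 0.791 with an estimated correlation. Without IL1RN TALE replicate 1, the only removal that left the IL-1 family cluster 5 measured genes, its call was lost and its median turned to −0.39, the value of PSD4. IL36B was not among those 5 genes, so the medians are not over the same members.

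Across all genes, edgeR called 0 of 18413 between IL1RN TALE and GFP, with 3 genes at an unadjusted p under 0.05 against 920.65 expected by chance, and DESeq2 called 0 genes, with 54 at that unadjusted level. The 3 were IL1RN, HRC and C19orf84. HRC, a calcium-binding protein of the sarcoplasmic reticulum, had 38 and 72 counts with the IL1RN TALEs, 14 and 6 with GFP and 12 with the HBG1 TALE (log2 fold change 3.16, SE 1.21). C19orf84 had 3 and 3 counts against 156 and 2, and 28 with the HBG1 TALE (log2 fold change −3.99, SE 1.77). Without GFP replicate 1 the C19orf84 value turned to 1.53. HRC and C19orf84 were named after their values were seen, to complete the count. The IL1RN TALE and GFP libraries did not overlap on log2 CPM in 1549 genes (8.41%), where chance gives 33.3%. Counts were simulated at the trend of this spread, without further variation between genes, which can overstate the shares found. Over the same 18413 genes, edgeR found 4% of genes raised 4-fold, 36% of those raised 16-fold, 96% of those raised 64-fold and 100% of those raised 256-fold in this comparison. Of genes lowered by the same folds it found 8%, 28%, 52% and 88%.

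Among 25 gene lists with at least 5 measured members, camera with a preset correlation called 4 higher and 3 lower with the IL1RN TALEs than with GFP, and 0 with an estimated correlation, with an adjusted p = 0.791 with an estimated correlation for each of the 7. Adjusted over the list alone, IL1RN in its own cluster was the sole call in these lists. Cytosolic ribosomal protein genes were called higher, with 72 of 75 members positive and a median log2 fold change of 0.49 (adjusted p = 7.23e-18). RPL31, for example, was 2565 ± 1115 CPM against 778 ± 784 (SD, n = 2 each), RPL27 had a log2 fold change of 1.89 and RPL34 of 1.62. Genes of the nuclear-encoded respiratory chain were called higher (31 of 36 positive, median 0.53, adjusted p = 6.04e-13), with NDUFA1 at 1.80, NDUFA6 at 1.78 and NDUFB3 at 1.67, all subunits of complex I. NF-kB targets and cytokines were called higher (11 of 16 positive, median 0.31, adjusted p = 0.0497), a call lost under 11 of its 12 alternatives and kept with GC and length offsets at an adjusted p of 0.0494. The cytokine IL32 led them at 3.62 ± 2.89 against 0.642 ± 0.0296 CPM (SD, n = 2 each, log2 fold change 2.48, SE 1.23), followed by CXCL8, which encodes interleukin-8, at 1.21 and RELB, an NF-kB subunit, at 0.82. Hypoxia and glycolysis genes were called lower (19 of 27 negative, median −0.22, adjusted p = 0.0415), with the glycolytic enzyme ALDOA at −0.78, the glucose transporter SLC2A3 at −0.57 and PDK1 at −0.51. Genes of G2/M and mitosis were called lower (adjusted p = 0.0415) with a mean of −0.08 although the median was 0.02 and 15 of 28 members were positive, and the mitotic regulators PLK1, CDC20 and CENPF stood at −1.33, −0.67 and −0.71. Developmental transcription factors were called lower (27 of 45 negative, median −0.05, adjusted p = 0.00927), with TBX5 at −2.91 and NEUROG2 at −1.24. No single member named here passed the test, and the SEs of their log2 fold changes ran from 0.77 to 1.97.

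Libraries of the same group also differed in these lists. The median difference of the ribosomal protein genes was −0.71 for IL1RN TALE replicate 1 minus GFP replicate 1, 1.30 for replicate 1 minus 2, 0.19 for replicate 2 minus 1 and 2.77 for replicate 2 minus 2, and −1.04 and 2.59 for replicate 1 minus 2 within the IL1RN TALE and the GFP group. For the respiratory chain the same 4 pairs gave −0.01, 0.69, 0.52 and 2.15, and −0.55 and 1.68 within the groups. For G2/M genes they gave −1.01, −0.53, 0.22 and 1.02, for hypoxia and glycolysis 0.26, −0.63, 0.35 and −0.72, for NF-kB targets 0.23, 1.04, −0.03 and 0.17, and for developmental transcription factors −0.52, −0.16, 0.07 and 0.55. Within the IL1RN TALE and the GFP group, replicate 1 minus 2 gave −1.26 and 0.76 for G2/M genes, −0.02 and −1.10 for hypoxia and glycolysis, 0.73 and 0.51 for NF-kB targets, and −0.50 and 0.59 for developmental transcription factors. Without GFP replicate 2, 0 lists were called, and without GFP replicate 1 the ribosomal, respiratory chain and hypoxia and glycolysis lists were the 3 called. Without GFP replicate 2 the ribosomal median turned to −0.28 and the hypoxia and glycolysis median to 0.16, and without IL1RN TALE replicate 1 the G2/M genes were called higher, at a median of 0.53. Without IL1RN TALE replicate 2 the ribosomal and respiratory chain calls were lost, at medians of −0.43 and 0.03. PLK1 and ALDOA turned to 0.78 and 0.27 without GFP replicate 2, TBX5 and NEUROG2 to 4.60 and 0.92 without GFP replicate 1, CDC20 to −0.051 and SLC2A3 to −0.20 without GFP replicate 2, CENPF to −0.22 and PDK1 to −0.29 without IL1RN TALE replicate 1, and RELB to −0.045 without IL1RN TALE replicate 1, where the NF-kB median was −0.33. Without IL1RN TALE replicate 2, IL32 was 1.21 and CXCL8 0.069. Without GFP replicate 2, RPL31, RPL27 and RPL34 were 0.75, 0.82 and 0.61, and NDUFA1, NDUFA6 and NDUFB3 were 0.97, 0.82 and 0.80. The median of developmental transcription factors turned to 0.11 without IL1RN TALE replicate 1 and to 0.39 without GFP replicate 1, and its call was lost in both. With library factors by the median of ratios, or with the replicate number as a block, the calls of the NF-kB, hypoxia and glycolysis and G2/M lists were lost, and 4 lists were called in each case, 3 higher and 1 lower.

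**Figure D2:**
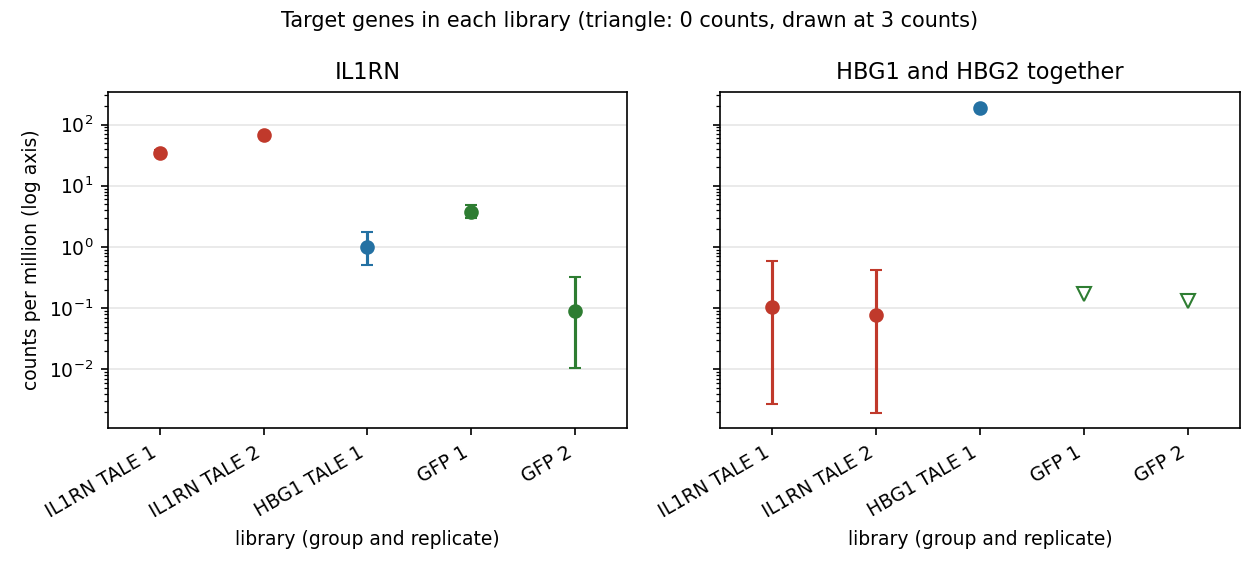
CPM (log axis) of IL1RN, left, and of HBG1 and HBG2 together, right, in each of the 5 libraries, with 95% exact Poisson limits that cover counting error only; open triangles mark 0 counts and are drawn at the CPM of 3 counts. IL1RN is 34.6 and 68.7 CPM in the IL1RN TALE libraries and at most 3.78 CPM in the other libraries, and HBG1 and HBG2 are 183 CPM in the HBG1 TALE library and at most 1 count in each of the others.

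With the HBG1 TALEs, HBG1 and its near-identical neighbour HBG2, the fetal gamma-globin genes, were read abundantly, while they had 0 counts in both GFP libraries. HBG1 (NM_000559) had 962 counts, or 80.0 CPM (75.01–85.2), and HBG2 (NM_000184) had 1245 counts, or 103.5 CPM (97.8–109). Taking 3 counts over the GFP group as the limit that 0 allows, HBG1 was at least 1075-fold and HBG2 at least 1391-fold higher than with GFP. The division of reads between these copies is uncertain, since how reads matching both were assigned is not given in the sources used here. Together they had 2207 counts, or 183 CPM (175.9–191), which is at least 2467-fold higher. The IL1RN TALE libraries held 1 and 0 counts on HBG1 and 0 and 1 on HBG2.

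The fitted log2 fold changes were 13.23 (SE 1.76) for HBG1 and 13.60 (SE 1.67) for HBG2. These depend on the prior count and are no bounds. In edgeR's quasi-likelihood test over all 18413 genes both had an adjusted p of 0.223, so neither was called, although they had the smallest p-values of the comparison. Both were called when the replicate number was a block (adjusted p = 0.0490 and 9.08e-04) and by DESeq2 (1.30e-08 and 3.71e-09), and edgeR called both, 2 genes, when any 1 of the 4 other libraries was left out. Over the alternatives for these genes the adjusted p ranged from 2.16e-10 to 1.

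Elsewhere in the beta-globin cluster the counts were low. Of 16 cluster genes, 4 passed the filter, and the 12 others held 81 counts in the 5 libraries together. HBB, the adult beta-globin, had 4 counts with the HBG1 TALE, 1 and 0 with the IL1RN TALEs and 2 and 0 with GFP, and HBE1, the embryonic globin, had 1, then 2 and 2, and 2 and 1. HBBP1, a globin pseudogene that lies between the gamma- and delta-globin genes, had 24 counts with the HBG1 TALE against 1 and 0 with GFP, a ratio of 80.5 (13.1–3309) with an adjusted p of 0.999, and 1 and 0 with the IL1RN TALEs. OR51B4, an olfactory receptor gene of the cluster, had 10 counts with the HBG1 TALE, 10 and 0 with GFP and 3 and 1 with the IL1RN TALEs. IL1RN was 1.71-fold (0.922–3.48) lower with the HBG1 TALE than with GFP on pooled counts, with a log2 fold change of −0.94 (SE 1.62, adjusted p = 0.999) that turned to 3.39 without GFP replicate 1.

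edgeR called 0 genes between HBG1 TALE and GFP, with 21 at an unadjusted p under 0.05 (19 higher and 2 lower, 920.65 expected by chance), while DESeq2 called 2, HBG1 and HBG2, with 269 at the unadjusted level. The HBG1 TALE library lay outside the range of the GFP libraries in 12072 genes (65.6%), where chance gives 66.7%. Simulated genes raised 4-fold, 16-fold, 64-fold and 256-fold in this comparison were found by edgeR in 0%, 16%, 88% and 96% of cases, and genes lowered by these folds in 0%, 8%, 32% and 56%. The same test did not call HBG1 and HBG2 in the real libraries, at bounds of 1075-fold and 1391-fold, so the simulated shares can overstate what it finds there.

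Camera with the preset correlation called 4 lists higher and 7 lower in the HBG1 TALE library than with GFP. With an estimated correlation 0 were called, with an adjusted p = 0.634 with an estimated correlation for ER chaperones and an adjusted p = 0.629 with an estimated correlation for the other lists named here. Adjusted over the list alone, 0 members were called in any list. All 75 ribosomal protein genes were negative, at a median log2 fold change of −1.59 (adjusted p = 9.31e-16), with RPL32 at −3.85, RPLP2 at −3.19 and RPS12 at −3.28. Of 36 respiratory chain genes 33 were negative (median −1.25, adjusted p = 7.10e-07), among them the complex I subunit NDUFS6 (−2.55) and the cytochrome c oxidase subunits COX5B (−2.16) and COX5A (−2.60). G2/M and mitosis genes were lower (27 of 28 negative, median −1.08, adjusted p = 1.23e-07), with securin, encoded by PTTG1, at −2.56, the kinetochore motor CENPE at −2.53 and the checkpoint gene MAD2L1 at −2.54. S-phase and DNA replication genes were lower (19 of 28 negative, median −0.40, adjusted p = 0.0368), with RFC4 at −2.50, SLBP at −2.26 and POLE2 at −1.97.

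Of the stress lists, 2 were called lower, while heat shock genes (median −0.51, adjusted p = 0.362) and NRF2 and oxidative stress genes (median 0.026, 10 of 19 positive, adjusted p = 0.425) were not called. The integrated stress response was called lower (18 of 22 negative, median −0.48, adjusted p = 0.00866), with DDIT3, which encodes CHOP, at 4.32 CPM against 48.1 ± 52.9 CPM (SD, n = 2), and with NUPR1 and CEBPB at log2 fold changes of −2.32 and −1.81. CEBPB turned to 0.0043 without GFP replicate 1. ER chaperones and unfolded protein response genes were called lower (17 of 20 negative, median −0.42, adjusted p = 0.0185), with DNAJB9 at −2.38, HERPUD1 at −1.25 and MANF at −1.52. Developmental transcription factors were called lower (30 of 45 negative, median −0.64, adjusted p = 0.00866), with NEUROG2 at −2.82, PAX6 at −1.61 and HOXA9 at −1.39.

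The lists called higher held markers of other cell types. Blood cell and macrophage markers were higher (12 of 13 positive, median 1.07, adjusted p = 0.00324), with CD74 at 1.41 CPM against 0.0884 ± 0.125 and CSF1R at 2.58 against 0.312 ± 0.122 CPM (SD, n = 2 each), and LYZ at 47.2 against 20.1 ± 21.0 CPM (SD, n = 2, log2 fold change 1.24). Endothelial markers were higher (9 of 11 positive, median 1.07, adjusted p = 0.00866), with CLDN5 at 2.59, ENG at 1.88 and ESAM at 1.07. Fibroblast and extracellular matrix markers were higher (18 of 22 positive, median 0.88, adjusted p = 0.0361), with the collagen COL5A2 at a log2 fold change of 1.25 and COL3A1 at 3.91 CPM against 1.37 ± 1.38 CPM (SD, n = 2), while the collagen cross-linking enzyme LOX stood at −1.32. The other globin and erythroid genes, which leave out the beta-globin cluster, were called higher (14 of 19 positive, median 0.94, adjusted p = 0.0429), with the red cell spectrin gene SPTB at 25.5 against 8.52 ± 9.02 CPM (SD, n = 2, log2 fold change 1.58) and TRIM58 at 39.2 against 18.6 ± 18.1 CPM (SD, n = 2, log2 fold change 1.08), while the theta-globin gene HBQ1 stood at −1.84. None of the members named for the 11 lists passed the test, and their SEs ran from 1.03 to 2.31. The HBG1 TALE library also had the highest share of olfactory receptor transcripts with a count and of ribosomal RNA among the 5 libraries, as given above.

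Set against each GFP library alone, the ribosomal protein median was −2.39 with GFP replicate 1 and −0.24 with GFP replicate 2, and the respiratory chain median −1.90 and −0.39. The G2/M median was −1.40 and −0.74, the integrated stress response −0.28 and −0.57, the S-phase list −0.32 and −0.29, and the ER chaperones −0.46 and −0.36. Blood markers gave 0.43 and 1.53, endothelial markers 0.44 and 1.58, fibroblast markers 0.76 and 0.44, and erythroid genes 0.32 and 0.85. The HBG1 TALE library and GFP replicate 2 lie on the same side of the GC difference, and the HBG1 TALE library and GFP replicate 1 on the same side of the olfactory receptor difference. GFP replicate 1 carried much of the size of many named genes on the lower side, less so for HERPUD1 and LOX. Without it, RPL32, RPLP2 and RPS12 were −0.17, −0.47 and −0.53, NDUFS6, COX5B and COX5A −0.88, −1.09 and −0.23, PTTG1, CENPE and MAD2L1 −0.79, −0.97 and −0.45, and RFC4, SLBP and POLE2 −0.90, −0.67 and −0.61. DDIT3 and NUPR1 were −1.29 and −1.08 there, DNAJB9, HERPUD1 and MANF −0.45, −0.89 and −0.47, NEUROG2, PAX6 and HOXA9 −0.66, −0.61 and −0.61, and HBQ1 and LOX −0.53 and −0.91. RPL32, for example, was 231 CPM with the HBG1 TALE, 6383 in GFP replicate 1 and 262 in GFP replicate 2. Of the genes on the higher side, CLDN5, ESAM, COL3A1 and SPTB were 1.68, 0.60, 0.75 and 0.79 without GFP replicate 1, and LYZ and TRIM58 were 0.26 and 0.15 without GFP replicate 2. Without GFP replicate 2, the ribosomal, respiratory chain and G2/M lists were the 3 called, and without GFP replicate 1 the calls of developmental transcription factors and fibroblast markers were lost. Offsets for GC content and length, chosen after the data were seen, ended the erythroid, S-phase, fibroblast and endothelial calls and brought the ribosomal and respiratory chain medians to −0.51 and −0.11. With the replicate number as a block, 5 lists were called, and the calls of the stress, ER chaperone, S-phase, erythroid, fibroblast and endothelial lists were lost.

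**Figure D3:**
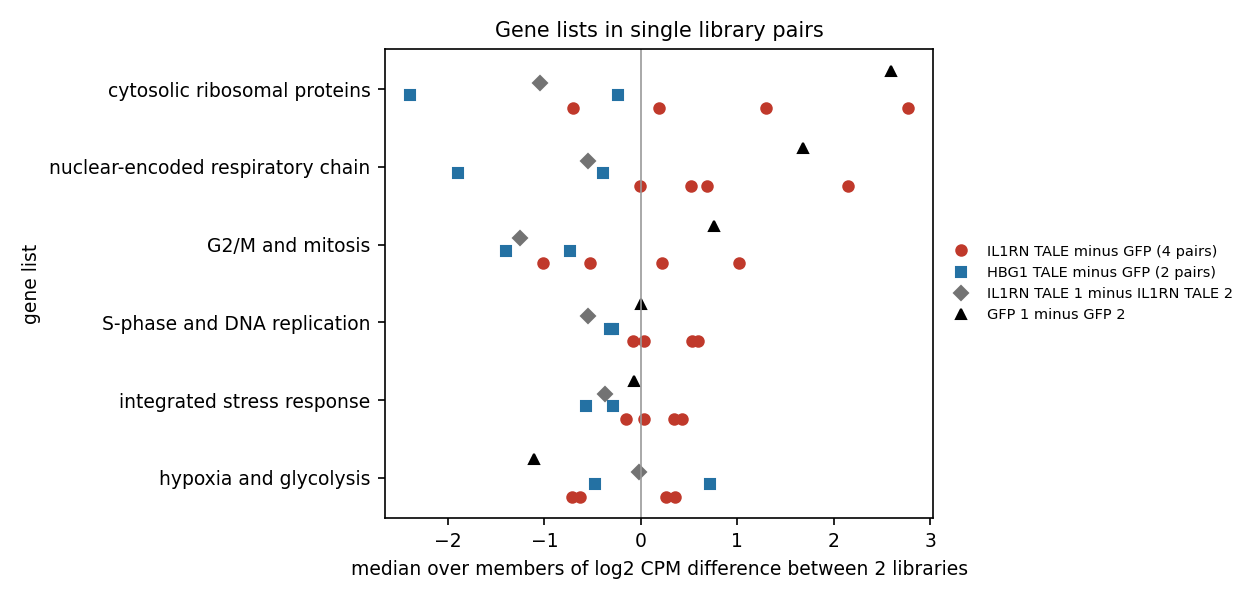
Median over the members of 6 gene lists of the log2 CPM difference between 2 libraries, for the 4 pairs of an IL1RN TALE and a GFP library (circles), the 2 pairs of the HBG1 TALE library and a GFP library (squares), and the 2 libraries of the same group (diamonds and triangles). The ribosomal protein median runs from −0.71 to 2.77 over the IL1RN TALE pairs and is 2.59 between the GFP libraries.

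The direct contrast of the TALE sets asked which genes differed between the activators. IL1RN was 54.5-fold (31.1–106) higher with the IL1RN TALEs than with the HBG1 TALE, and the single libraries were 34.7-fold and 68.9-fold higher. Its log2 fold change was 5.68 (SE 2.04, adjusted p = 0.983). HBG1 and HBG2 together were 2069-fold (572–17092) lower with the IL1RN TALEs, which held 2 counts against 2207. The fitted values were −10.52 (SE 1.56, adjusted p = 0.555) for HBG1 and −10.97 (SE 1.49, adjusted p = 0.541) for HBG2. No gene was called by edgeR (0 genes, with 42 at an unadjusted p under 0.05, 35 higher and 7 lower with the IL1RN TALEs), and DESeq2 called 2, HBG1 and HBG2, with 1007 at the unadjusted level. Without GFP replicate 1 or without GFP replicate 2, edgeR called HBG1 and HBG2, 2 genes in each case, and it called 0 genes without IL1RN TALE replicate 1, without IL1RN TALE replicate 2 and with the replicate number as a block (lowest adjusted p 0.384, 0.306 and 0.389). In 14367 genes (78.0%) the HBG1 TALE library lay outside the range of the IL1RN TALE libraries, where chance gives 66.7%. Simulated genes raised 4-fold, 16-fold, 64-fold and 256-fold in this contrast were found by edgeR in 0%, 20%, 64% and 92% of cases, and genes lowered by these folds in 0%, 36%, 64% and 68%.

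Camera called 5 lists higher and 3 lower with the IL1RN TALEs than with the HBG1 TALE, and 0 with an estimated correlation (adjusted p = 0.769 with an estimated correlation for each of the 8). Adjusted over the list alone, 0 members were called. Ribosomal protein genes were positive in 75 of 75 (median 2.50, adjusted p = 3.31e-26), with RPL39 at 2124 ± 125 CPM (SD, n = 2) against 193 CPM, and RPL37A at a log2 fold change of 2.99. Respiratory chain genes were positive in 32 of 36 (median 2.18, adjusted p = 3.49e-13), with NDUFA1 at 222 ± 89.8 CPM (SD, n = 2) against 25.2 CPM, and NDUFB3 and NDUFB5 at 2.86 and 3.22. G2/M genes were higher (24 of 28 positive, median 1.14, adjusted p = 5.76e-04), with the mitotic kinase CDK1 at 2.82, PTTG1 at 2.84 and MAD2L1 at 2.93, as were S-phase genes (20 of 28, median 0.62, adjusted p = 0.0176), with RFC4 at 3.21, POLE2 at 2.57 and SLBP at 2.72. The integrated stress response was higher (18 of 22 positive, median 0.55, adjusted p = 0.0158), with NUPR1 at 2.81, DDIT3 at 3.31 and the asparagine synthetase gene ASNS at 2.60. Blood markers were lower (12 of 13 negative, median −1.28, adjusted p = 0.00283), with CD14 at −3.06, CSF1R at −2.34 and PTPRC at −1.89. Endothelial markers were lower (10 of 11 negative, median −0.81, adjusted p = 0.0158), with CLDN5 at −3.43, EMCN at −1.71 and PECAM1 at −1.21. The other globin and erythroid genes were lower (15 of 19 negative, median −0.95, adjusted p = 0.0331), with TRIM58 at −1.20, while HBQ1 stood at 2.58. None of these members passed the test, and their SEs ran from 1.22 to 1.92.

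Each IL1RN TALE library set against the HBG1 TALE library gave the same directions at different sizes. Replicates 1 and 2 gave ribosomal protein medians of 1.65 and 2.58, respiratory chain medians of 1.39 and 2.42, G2/M medians of 0.34 and 1.63, blood marker medians of −0.51 and −2.43 and endothelial marker medians of −0.26 and −2.42. IL1RN TALE replicate 2 carried much of the size of many named genes. Without it, PTTG1, CDK1 and MAD2L1 were 2.13, 1.97 and 1.43, RFC4, POLE2 and SLBP 1.61, 1.31 and 1.53, NUPR1, DDIT3 and ASNS 1.77, 0.97 and 0.68, and HBQ1 0.72. CD14, CSF1R and PTPRC were −2.02, −1.43 and −1.06 there, CLDN5, EMCN and PECAM1 −2.72, −0.73 and −0.41, and TRIM58 −0.49. ASNS, for example, was 189 and 1246 CPM in the IL1RN TALE libraries against 118 CPM, and EMCN 7.70 and 0.153 against 12.8 CPM. In GFP replicates 1 and 2 EMCN was 11.4 and 0.354 CPM, PECAM1 6.89 and 1.19, PTPRC 3.05 and 0.133, and TRIM58 31.4 and 5.75. These genes were higher in every library with a high olfactory receptor share than in the others, whichever plasmid was used. CD14, CSF1R and CLDN5 broke this order. IL1RN TALE replicate 1 and the HBG1 TALE library lie on the same side of both library differences. With the replicate number as a block, 4 of the lists were called, and the calls of the stress, S-phase, erythroid and endothelial lists were lost. Without IL1RN TALE replicate 2, 4 lists were called, and the G2/M, S-phase, stress and endothelial calls were lost. The GC and length offsets brought the ribosomal and respiratory chain medians to 0.85 and 0.70 and ended the endothelial call. The erythroid call was lost without IL1RN TALE replicate 1, GFP replicate 1 or GFP replicate 2.

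The responses to the 2 TALE sets were compared across the 18413 tested genes as differences of group means of log2 CPM. They correlated at r = −0.125 (Spearman's rho −0.109, covariance −0.0642) and had the same sign in 48.7% of genes. Because both use the same GFP libraries, unchanged groups would correlate by chance, and 100 simulations of unchanged groups against these controls gave r = 0.401 (0.383–0.414), a covariance of 0.552 (0.525–0.576) and the same sign in 63.1%. The observed covariance lay below the simulated one by a difference of −0.616. The simulated libraries were drawn independently, without the GC and olfactory receptor differences seen here, so their range does not cover such differences and the shortfall is no evidence of opposite responses. No call was shared in either direction (0 higher and 0 lower, 0 expected for independent lists), as edgeR called 0 genes in both comparisons. The correlation was −0.698 without IL1RN TALE replicate 1, 0.666 without IL1RN TALE replicate 2, 0.405 without GFP replicate 1 and 0.578 without GFP replicate 2, so single libraries set its sign. With 2 control libraries, the controls could not be split so that each part kept 2, so part of any correlation may come from the shared controls.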

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

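The offsets on GC content and length, the crossed block, the transcript rows and the fitted fold changes were tests chosen after the data were seen; the others were planned. Between IL1RN TALE and GFP the count of genes was 0 under 17 of 18 alternatives and 1, IL1RN, without GFP replicate 1 (range without single libraries 0 to 1). IL1RN kept its direction under all 17 of its alternatives, at a log2 fold change of 3.58 to 9.06 without single libraries. Between HBG1 TALE and GFP, 0 genes were called under 7 of 17 alternatives and 2, HBG1 and HBG2, under 10, including each library left out (2 to 2). The 2 calls came with RLE factors, no filter, the replicate block, DESeq2, only the 2 groups, and the offsets with the replicate block, where HBG1 was 13.20, 13.19, 12.31, 13.02, 13.46 and 14.50 (12.98 to 13.36 without single libraries) and HBG2 13.58, 13.56, 15.00, 13.39, 13.83 and 15.56 (13.35 to 13.73). Between IL1RN TALE and HBG1 TALE, 2 genes, HBG1 and HBG2, were called with RLE factors, no filter, DESeq2, only the 2 groups, and the offsets with the replicate block, and 0 to 2 without single libraries. HBG1 was −10.55, −10.50, −10.80, −10.47 and −10.70 there (−13.36 to −9.45 without single libraries) and HBG2 −10.98, −10.94, −11.20, −10.90 and −14.06 (−13.59 to −10.27). For HBG1 TALE against GFP, the gene-level edgeR settings with calls had infinite or 21.4 prior degrees of freedom, so they shared the spread more among genes, and those without calls had 3.14 to 9.01. The filter of 50 counts in 3 libraries removed HBG1 and HBG2 from the 13429 genes tested. Adjusted p-values of the target genes ranged from 2.16e-10 to 1.

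Called lists between IL1RN TALE and GFP numbered 4 with RLE factors (3 higher and 1 lower, where TMM gave 4 and 3), 4 with the replicate block, 0 with an estimated correlation, 0 with fry and 0 to 7 without single libraries. Between HBG1 TALE and GFP they numbered 5 with the replicate block, 0 with an estimated correlation, 0 with fry and 3 to 13 without single libraries. Between the TALE sets they numbered 4 with the replicate block, 5 with the offsets and the block, 0 with an estimated correlation, 0 with fry and 4 to 8 without single libraries. The correlation of the TALE responses was −0.0032 with the crossed block, 0.0216 from fitted fold changes and −0.698 to 0.666 without single libraries. The cause of these changes was not tested.

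Values that reversed did so mostly without single libraries, over which the log2 fold changes with the IL1RN TALEs against GFP were −0.39 to 2.95 for PSD4, −0.045 to 1.38 for RELB, −2.22 to 0.78 for PLK1, −1.44 to 0.27 for ALDOA, −7.70 to 4.60 for TBX5, −2.25 to 0.92 for NEUROG2 and −5.17 to 1.53 for C19orf84. The list medians there were −0.83 to 0.54 for G2/M, −0.60 to 0.16 for hypoxia and glycolysis, −0.43 to 2.385 for ribosomal proteins, −0.42 to 0.39 for developmental transcription factors, −0.33 to 0.82 for NF-kB targets, and −0.39 for the IL-1 family cluster in its only possible removal. In that removal IL36B was no longer among the cluster's measured members. With the HBG1 TALE against GFP the ranges were −2.76 to 0.0043 for CEBPB and −2.08 to 3.39 for IL1RN. IL1RN with the HBG1 TALE against GFP was 1.39 with the crossed block. Of 1282 values for 81 other named results, 1272 kept their direction and 10 reversed. None of these results was called in the main test or under any alternative, so staying uncalled says nothing of stability. The adjusted p under 0.01 and the test against a fold change of 1.5 reuse the main fit and could not change a direction or add a called gene. Sizes moved far, as for RPL32 with the HBG1 TALE against GFP, at −4.96 to −0.17 without single libraries. Of 289 values for 26 list results, 166 kept their call, 120 lost it and 3 reversed. The same-numbered deviations correlated at r = −0.1003, over 2 pairs that carry the same information, while a principal component with 37.3% of the variance and the olfactory receptor counts separate the numbers, so whether the numbers pair the libraries stays open. The block raised the gene count from 0 to 2 between HBG1 TALE and GFP and changed the gene count of no other comparison. With the crossed pairing, 0, 0 and 0 genes and 5, 11 and 8 lists were called in the 3 comparisons. Of the 9 planned removals of single libraries, 5 were possible, and without the HBG1 TALE library no contrast with that group exists. Where a removal leaves 1 library in a group, it is assumed to vary like the other groups. Depth limits what can be said of genes near 3 counts per group, where neither presence nor absence was detectable.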

Other observations

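Of the tests below, those of GC content and length offsets and of other silent gene families were written before their results were seen, and the others were chosen after the result was seen. The genes in this paragraph were singled out after their values were seen, and none was called. With the HBG1 TALE, the adipocyte lipid-droplet gene PLIN4 had 400 counts against 13 and 68 with GFP and 116 and 10 with the IL1RN TALEs (log2 fold change against GFP 4.14, SE 1.49, adjusted p = 0.999 in edgeR). The kidney phosphate transporter gene SLC34A3 had 57 counts against 0 and 1 with GFP and 7 and 0 with the IL1RN TALEs. The muscle glycogen phosphorylase gene PYGM had 113 counts against 8 and 38 with GFP and 12 and 6 with the IL1RN TALEs. BCYRN1, the small cytoplasmic BC200 RNA, had 111 counts against 7277 and 572 with GFP (log2 fold change −4.56, SE 2.05) and 264 and 3817 with the IL1RN TALEs. Its counts were higher in both libraries low in GC-rich genes than in the 3 others. PLIN4 and PYGM went the other way, with lower counts in those libraries than in each of the 3 others. SLC34A3 did so too, at 0 counts in both.

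Lists of other responses to transfection or damage were not called by camera in any comparison. The GFP cells also received plasmids by lipofection, so a response to transfection shared by all groups would not show in these contrasts. Interferon-stimulated genes, which respond to foreign nucleic acid among other signals, had a median log2 fold change of 0.24 with the IL1RN TALEs against GFP (18 of 27 positive, adjusted p = 0.334) and 0.51 with the HBG1 TALE (16 of 27, adjusted p = 0.425). p53 targets stood at −0.07 in both (8 of 22 positive in each, adjusted p = 0.334 and 0.360). Heat shock genes stood at 0.27 (14 of 21 positive, adjusted p = 0.233) and −0.51 (8 of 21, adjusted p = 0.362), and genes of IL-1 signalling at 0.18 (9 of 13 positive, adjusted p = 0.421) and 0.59 (9 of 13, adjusted p = 0.392).

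The libraries did not group by plasmid: same-group pairs had a mean r of 0.873 across genes and pairs from different groups 0.905, a difference of −0.0319 (−0.0652 without TMM, over genes with more than 200 counts). Besides the GC trends given above, Spearman's rho with transcript length was 0.032 and −0.27 in IL1RN TALE 1 and 2, 0.23 in HBG1 TALE 1, and −0.19 and 0.20 in GFP 1 and 2. An effect of the transfected factors as the whole cause is argued against by the GC trend: Spearman's rho with GC content differed by 0.776 within the IL1RN TALE group and by 1.14 within the GFP group, and by at most 0.579 between group means, although these trends are part of the pattern itself. The GFP pair's r of 0.839 lies above the lowest r of pairs from different groups, 0.829, and decides nothing. Offsets for GC content and length brought the difference to −0.0186, with same-group pairs at 0.907 and others at 0.925. That is smaller but still below 0, so bias of single libraries may account for part of the separation and cannot be told apart from other library differences with 5 libraries.

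Counts on olfactory receptor genes stood out in IL1RN TALE replicate 1, the HBG1 TALE library and GFP replicate 1. Activation by the TALEs as the whole cause is argued against by the GFP pair, whose olfactory receptor CPM differed 6.03-fold (5.23–6.97) within the control group, and by the IL1RN TALE pair at 11.6-fold. These ratios are, however, part of the pattern itself. Depth is argued against by the same 6.03-fold, since the GFP totals differed by 1.04 times. Reads from DNA rather than RNA are a candidate explanation: in 4 of 5 other families of silent genes each of these 3 libraries exceeded each of the other 2, for example interferon alpha genes at 2.32, 3.73 and 2.49 CPM against 0.121 and 0.106, although bitter taste receptors in the IL1RN TALE pair overlapped within counting error (9.07 and 7.53) and vomeronasal receptors broke the order. The labels report DNase digestion, and whether genomic DNA or another source of intergenic reads was present was not tested.

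IL1RN had 67 counts in GFP replicate 1 and 2 in GFP replicate 2, and without GFP replicate 1 IL1RN was called, at a log2 fold change of 9.06. An exchange of reads between all libraries is argued against, because HBG1 and HBG2 counts in the other 4 libraries were 0.0906% (0.011–0.327) of those in the HBG1 TALE library, while IL1RN in GFP replicate 1 was 5.46% of the IL1RN TALE counts. Background on silent genes stays open: IL1RN, at 34.9 counts per kilobase, lay above 99.2% of 373 olfactory receptor transcripts in that library. It stood at 20.4 times their median, yet their highest reached 78.8. The HBG1 TALE library had more olfactory receptor CPM than GFP replicate 1 (138 against 71.8, on raw totals) but less IL1RN (0.998 against 3.78 CPM). A background that follows the olfactory receptor counts would not give this order, although each is a single library. Carry-over from an IL1RN TALE library stays open too: the counts over the 4 transcripts were 23, 22, 9 and 13, against 300, 295, 329 and 302 in both IL1RN TALE libraries together (2-sided Fisher exact p = 0.0188), a difference too weak to exclude it. Expression of IL1RN in the cells of this library stays among the open explanations, untested.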
